A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

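Newly made RNA of budding yeast was measured by 4tU-seq. In it, cells take up the labelling compound 4tU for a few minutes, and the RNA that carries it is isolated and sequenced. The strain is haploid and of mating type alpha. Its chromosomal SRB10 gene (SSN3 in the gene tables) is deleted, and a TRP1 plasmid carries srb10as-1, a form of the Mediator kinase Srb10 (Cdk8) made sensitive to the ATP analogue 1-NA-PP1. Cultures grew at 30 °C from an OD600 of 0.1 to one of 0.8 and then received 6 µM 1-NA-PP1 or the solvent DMSO for 12 minutes. Some cultures were then held at 37 °C (heat shock) for 12 minutes, and the others are called steady state. Labelling was with 5 mM 4tU for 5 minutes, and each library started from 100 ng RNA. The labels give 4 groups of 2 libraries and do not say whether the replicates were separate cultures, so they may be technical.

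The authors deposited raw counts, whole numbers of reads per open reading frame transcript, for 4928 features on 16 chromosomes of the build sacCer3. The labels name cutadapt 1.9.1, STAR 2.5.2b, SAMtools, HTSeq and DESeq2 without their order or settings, and do not state whether reads were counted by strand. The deposited normalised tables hold a signal, the raw count divided by 1 factor per library. The deposited factor files hold each factor as a ratio to the first library of the table. How the authors estimated these factors is not stated. At steady state the deposited factors are 1, 0.91, 0.946 and 1.46, where median-of-ratios factors from the raw counts are 0.940, 1.02 and 0.975 relative to the first library. For 1-NA-PP1 against DMSO under heat shock, the deposited file holds 1, 0.91, 0.326 and 0.218, which are the numbers of the DMSO steady state and heat shock file, while the deposited normalised counts follow from factors of 1, 0.621, 1.10 and 1.57. The authors' deposited tables for the heat shock comparisons give, per the file headers, a log2 fold change of heat shock over steady state. Per the file headers they also give an adjusted p value (unit p_value) per gene, after the authors' factors. Other deposited files (unit other) hold transcript coordinates and the authors' own lists of heat shock response genes, without values.

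Of the 4928 features, 4842 matched a gene of the reference table by systematic name and overlapped it. Features missing from that table or called dubious in it numbered 88, and 1692 features overlap one on the opposite strand. Values of such overlapping genes are uncertain, since the strand of counting is not stated, and they are marked below as having an antisense neighbour. A total of 5 features had 0 counts in every library. No feature of the mitochondrial genome is among them, so 0 of the 22 genes of that list were measured.

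Raw counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr left 4901 genes, TMM factors scaled the libraries, and 1 quasi-likelihood model of the 4 groups was fitted to all 8 libraries. Tests were two-sided, and a gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The comparisons were 1-NA-PP1 against DMSO at steady state and under heat shock, heat shock against steady state with DMSO and with 1-NA-PP1, and the difference between these changes. With 2 libraries per group an exact permutation test cannot go below a two-sided p of 0.33, so each adjusted p printed comes from a model fitted across all genes. CPM are edgeR's depth-normalised counts (cpm) after TMM scaling, given as mean ± SD with n = 2. Log2 changes are relative to the bulk of genes, as TMM sets it, and do not measure a change of total RNA synthesis.

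Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, with the adjustment over the 26 lists. The test was repeated with the correlation between genes estimated from the data. The lists were Hsf1 core targets, Msn2/Msn4 general stress genes, trehalose and glycogen metabolism, cytoplasmic ribosomal proteins, ribosome biogenesis factors, RNA polymerase I and III subunits, Gcn4 targets, Ste12 targets, glucose-repressed genes, glycolysis, nuclear genes of respiration, proteasome, unfolded protein response, cell wall integrity, Yap1 targets of oxidative stress, multidrug resistance, iron regulon, phosphate regulon, ergosterol synthesis, core histones, G1/S genes, G2/M genes, the Mediator kinase module, other Mediator subunits, RNA polymerase II subunits, mating type a genes, mating type alpha genes, meiosis genes, the mitochondrial genome and a genotype check. Both lists of the authors were tested apart from these. Calls of list members are given over all genes tested and adjusted over the list alone.

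The lists, the comparisons, the tests and a rule for the genes to name were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of both groups, up to 4 members of each list by p, the kinase module, the genotype genes, and HSP104, SSA4, HSP26, HSP12, CTT1 and BTN2.

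In simulated data 86.6% of genes changed 1.5-fold were recovered for 1-NA-PP1 at steady state and 79.1% under heat shock. At 2-fold these were 100% and 97%. Calls among unchanged genes were 17 of 4669 and 8 of 4668. In real data RSB1 (3.31-fold, steady state) and GRE1 (2.13-fold, heat shock) were uncalled, so recovery does not carry over. Alternatives fixed with the tests were DESeq2 factors, library totals, DESeq2 1.42.0 (Wald test), fits of only the libraries compared, the deposited factors, no filter, a replicate block, a 2-fold minimum, an estimated correlation, and leaving out each library in turn. In fits that leave a group with 1 library, that library is assumed to vary like the other groups. Alternatives chosen after seeing the data were voom with library quality weights, counts thinned to the shallowest library, the factors behind the deposited normalised counts, DESeq2 with the deposited factors, and a crossed pairing of replicates. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

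A count of 0, taken to allow up to 3 counts, corresponds to at most 0.0497 CPM in a steady state library and 0.204 in a heat shock library. Such limits cover counting error only.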

Results

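Newly made RNA was counted for 4928 transcripts in 8 libraries, with 2 libraries in each of 4 groups: DMSO or 1-NA-PP1, each at steady state or under heat shock. Total counts were 64682858 and 60372371 for DMSO at steady state and 65134744 and 61566972 for 1-NA-PP1 at steady state. Under heat shock they were 17743527 and 14680275 with DMSO and 17137998 and 17413120 with 1-NA-PP1. The median count per gene was 6501 to 7099.5 in the steady state libraries and 1329.5 to 1615 in the heat shock libraries, and the 10 genes with the most counts took 4.68% to 7.02% of a library.

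ADE2, LEU2, MET17 and URA3, genes of adenine, leucine, methionine and uracil synthesis, had 0 counts in all 8 libraries, where a count of 0 allows up to 0.204 CPM in the shallowest. HIS3 and LYS2, the other markers, are not among the features. SSN3, which encodes Srb10 and is carried on the plasmid, lies on chromosome XVI at 472932 to 474951 and had 2440 ± 2.25 CPM with DMSO at steady state (n = 2). SSN8, the gene of its cyclin, had 103 ± 0.228 CPM in the same libraries, and the plasmid marker TRP1 had 70.6 ± 0.943. The other genes of the kinase module, SRB8 and SSN2, are not among the features.

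Heat shock and steady state libraries lay apart on the first principal component, which held 77.1% of the variance. The second held 12.1% and separated 1-NA-PP1 steady state replicate 2, at 18.9, from replicate 1, at 3, and from the DMSO libraries at -7.29 and -9.82. Across genes, which are not independent replicates, the log2 CPM of replicates correlated with r = 0.9985 for DMSO and 0.9918 for 1-NA-PP1 at steady state, and with 0.9926 and 0.9948 under heat shock. The median absolute log2 difference between replicates was 0.06, 0.13, 0.13 and 0.09 in the same order.

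**Figure D1:**
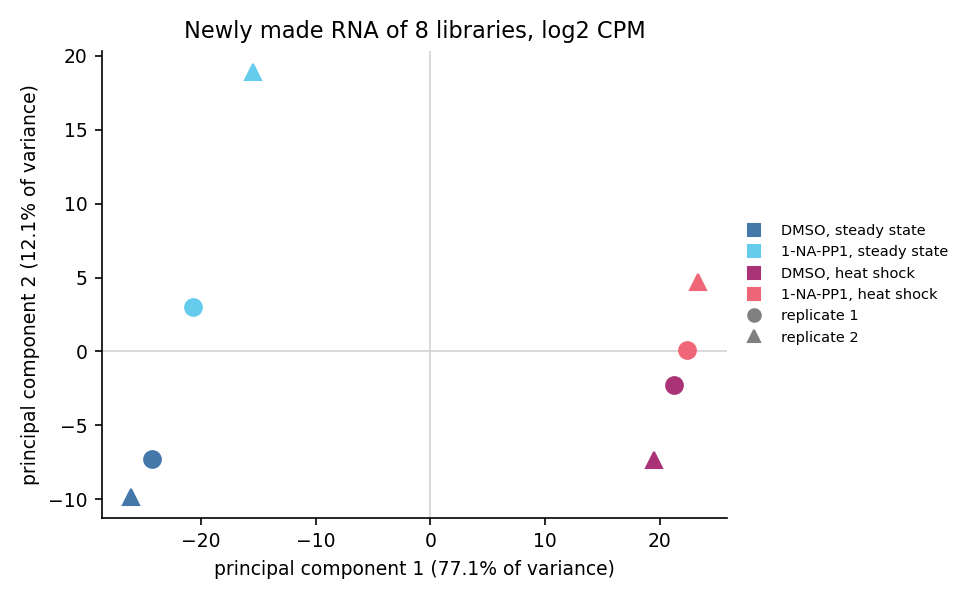
Scores of the 8 libraries on the first (77.1% of variance) and second (12.1%) principal components of log2 CPM, one point per library, coloured by group, with a circle for replicate 1 and a triangle for replicate 2. Heat shock libraries lie at 19.5 to 23.4 on the first component, steady state libraries at -26.1 to -15.4.

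The first comparison addressed what inhibition of Srb10 does to newly made RNA in growing cells. No gene passed the test, while gene groups moved together: Msn2/Msn4 general stress genes, which protect cells under many stresses, were higher as a group with 1-NA-PP1, and ribosome biogenesis factors, which assemble ribosomes, were lower as a group. With an estimated correlation 0 of the 26 lists passed, the smallest adjusted p being 0.45. General stress genes had a median log2 change of 0.79 and ribosome biogenesis factors of -0.72. Both 1-NA-PP1 libraries lay on the same side of the DMSO mean, with general stress medians of 0.49 and 1.04 and ribosome biogenesis medians of -0.44 and -1.09 in replicates 1 and 2. Without replicate 2 the median changes were 0.49 and -0.44, and without replicate 1 the ribosome biogenesis median was -1.09. Chaperone genes under Hsf1 and Gcn4 targets of amino acid synthesis were lower as groups too, and multidrug resistance genes were higher, each with adjusted p = 0.45 with an estimated correlation.

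Of the 23 general stress genes tested, 0 were called over all genes and 16 were higher and 0 lower when adjusted over the list alone. The list passed camera at adjusted p = 3.19e-08, and had adjusted p = 0.471 with an estimated correlation; without 1-NA-PP1 replicate 2 its median was 0.49. RTN2, a reticulon-like gene of the endoplasmic reticulum with an antisense neighbour, had 263 ± 30.6 CPM with DMSO and 594 ± 218 with 1-NA-PP1 (n = 2), a log2 change of 1.17 (SE 0.225, adjusted p = 0.0679). XBP1, a stress-induced repressor of transcription, had a log2 change of 0.79, the catalase gene CTT1 1.13 and the small chaperone gene HSP26 1.18, each with adjusted p = 0.0679. HSP12, a membrane-protecting stress protein gene, had 0.96 (adjusted p = 0.0686). Genes of trehalose and glycogen, the storage sugars, were higher as a group (13 tested, median 0.35, 13 positive; adjusted p = 0.000607, and 0.586 with an estimated correlation). Over all genes 0 of them were called, and 3 were higher adjusted over the list alone. GLG2 and GLG1, which prime glycogen synthesis, had log2 changes of 0.38 and 0.37, and without 1-NA-PP1 replicate 2 this list's median was 0.19.

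Of the 48 ribosome biogenesis factors all were negative, and 47 were lower adjusted over the list alone (adjusted p = 1.38e-30, and 0.45 with an estimated correlation). EBP2, needed for the large subunit and located on chromosome XI at 125740 to 127141, had 470 ± 38.9 CPM with DMSO and 295 ± 54.6 with 1-NA-PP1 (log2 change -0.67, SE 0.129, adjusted p = 0.0679). NOP8, another assembly factor, with an antisense neighbour, had -0.69. Ribosomal protein genes were lower as a group (134 tested, 133 negative, 112 lower adjusted over the list alone, median -0.50; adjusted p = 1.18e-35, and 0.45 with an estimated correlation). RPL26B and RPL14B, which each have a near-identical paralog that can share reads, had -0.50 and -0.39. Subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, had a median of -0.50, with 18 of 18 negative and 16 lower adjusted over the list alone (adjusted p = 2.07e-11, and 0.45 with an estimated correlation). RPC53 and RPC34 had -0.51 and -0.74. Without 1-NA-PP1 replicate 2 the medians of ribosome biogenesis and ribosomal protein genes were -0.44 and -0.27, and without replicate 1 they were -1.09 and -0.77. In these lists and in the others at steady state, 0 members were called over all genes.

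Gcn4 targets of amino acid synthesis were lower as a group, with 37 of 37 negative, a median of -0.37 and 30 lower adjusted over the list alone (adjusted p = 6.36e-15, and 0.45 with an estimated correlation). CPA1, of arginine synthesis, had -0.56, and without 1-NA-PP1 replicate 2 the median was -0.24. Hsf1 core targets, which encode protein chaperones, had a median of -0.28, with 21 of 22 negative and 13 lower adjusted over the list alone (adjusted p = 2.78e-08, and 0.45 with an estimated correlation). The co-chaperone gene STI1 had 2400 ± 48.7 CPM with DMSO and 1850 ± 106 with 1-NA-PP1 (log2 change -0.38), and CUR1, a sorting factor of misfolded proteins, had -0.30. Among the heat shock markers of this kind, HSP104, the disaggregase, had -0.23 (adjusted p = 0.182), BTN2 -0.15 (adjusted p = 0.274) and SSA4, an inducible Hsp70, 0.16 (adjusted p = 0.463; -0.13 with the deposited factors). Yap1 targets of oxidative stress were lower as a group (19 tested, 16 negative, 1 higher and 3 lower adjusted over the list alone, median -0.21; adjusted p = 0.000607, and 0.45 with an estimated correlation). CCP1, cytochrome c peroxidase, had -0.44 and ZWF1, of NADPH supply, -0.35. RNA polymerase II subunits were lower as a group (11 tested, 9 negative, 2 lower adjusted over the list alone, median -0.10; adjusted p = 0.035, and 0.471 with an estimated correlation), and RPB5, with an antisense neighbour, had -0.37. That group's call was lost without DMSO replicate 2 (median -0.06, adjusted p = 0.158) and without 1-NA-PP1 replicate 1 (adjusted p = 0.126), and its median was -0.15 without DMSO replicate 1.

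Glucose-repressed genes, used on poorer carbon sources, were higher as a group (25 tested, 21 positive, 6 higher and 1 lower adjusted over the list alone, median 0.33; adjusted p = 0.00334, and 0.586 with an estimated correlation). CYB2, lactate dehydrogenase, had a log2 change of 0.94 and the peroxisomal thiolase gene POT1, with an antisense neighbour, 1.35, while the hexose transporter gene HXT2 had -0.76. Multidrug resistance genes had a median of 0.40, with 9 of 9 positive and 7 higher adjusted over the list alone (adjusted p = 1.61e-05, and 0.45 with an estimated correlation). RSB1, a transporter of sphingolipid bases, had 20.3 ± 0.357 CPM with DMSO and 67.2 ± 39.2 with 1-NA-PP1, and TPO1, a polyamine exporter, had a log2 change of 0.38. Proteasome genes had a median of 0.21, with 32 of 32 positive and 5 higher adjusted over the list alone, and -0.08 with the deposited factors (adjusted p = 2.13e-05, and 0.586 with an estimated correlation). RPN2 and RPN7, of the regulatory particle, had 0.32 and 0.26, the latter -0.02 with the deposited factors. Nuclear genes of respiration had a median of 0.15, with 35 of 37 positive and 5 higher adjusted over the list alone, and -0.12 with the deposited factors (adjusted p = 0.00309, and 0.586 with an estimated correlation). CYC7 and NDI1, of electron transport, both with antisense neighbours, had 1.35 and 0.37. G1/S genes of the cell cycle had a median of 0.12, with 20 of 21 positive and 2 higher adjusted over the list alone, and -0.14 with the deposited factors (adjusted p = 0.0388, and 0.678 with an estimated correlation). The cyclin gene CLN1 had 0.33 and the replication gene CDC6 0.37. Without 1-NA-PP1 replicate 2 the glucose-repressed and proteasome medians were 0.16 and 0.12, and without replicate 1 the multidrug resistance median was 0.61. Without DMSO replicate 1 the respiration call was lost (adjusted p = 0.0546), and the G1/S call was lost without DMSO replicate 2 (adjusted p = 0.238) or 1-NA-PP1 replicate 1 (adjusted p = 0.346).

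SSN3, which this strain carries only on the plasmid, had a log2 change of 0.39 (SE 0.092, adjusted p = 0.0679), SSN8 had 0.30 (adjusted p = 0.07) and TRP1 0.28 (adjusted p = 0.201; -0.02 with the deposited factors). The authors' list of heat shock response genes, chosen in a study of these samples and so not independent evidence, had a median of 0.35 (22 tested, 18 positive, 13 higher and 1 lower adjusted over the list alone; adjusted p = 3.39e-05, and 0.293 with an estimated correlation). Their induced heat shock genes had a median of 0.71 (13 tested, 11 higher and 1 lower adjusted over the list alone; adjusted p = 2.98e-06, and 0.293 with an estimated correlation). Without 1-NA-PP1 replicate 2 the induced genes had 0.46. BDH2, a putative alcohol dehydrogenase gene on these lists, had 104 ± 13.6 CPM with DMSO and 318 ± 159 with 1-NA-PP1.

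In edgeR 0 of 4901 genes were called for 1-NA-PP1 at steady state, with a smallest adjusted p of 0.0679. At an unadjusted p under 0.05 there were 1608 genes, 874 higher and 734 lower, where chance alone gives 245. DESeq2 called 986 genes (426 higher, 560 lower) and voom with quality weights 749 (281 higher, 468 lower). Without 1 library, edgeR had calls only in the fit with 1-NA-PP1 replicate 2 alone. Of the 26 lists 14 passed camera and 0 with an estimated correlation. The other 12 did not pass with all libraries, and glycolysis did without 1-NA-PP1 replicate 2 (adjusted p = 0.178 with all, 0.00935 without it).

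Under heat shock, inhibition of Srb10 was compared with DMSO in cells at 37 °C. Genes that rose with 1-NA-PP1 included YDL218W, which encodes a membrane protein of unknown function, HAP4, the activator subunit that controls respiration genes, and CLN1, a G1 cyclin gene. Genes that fell included ARO9 and ARO10, of aromatic amino acid breakdown, ARG4, of arginine synthesis, and CCP1, cytochrome c peroxidase. With the deposited factor file the log2 changes of these 4 turn to 1.08, 1.24, 1.20 and 1.36. That file holds the numbers of the DMSO steady state and heat shock comparison and moves the median of all genes to 1.98. Turns with it, here and below, follow from this shift and do not test single genes or lists. With the factors behind the normalised counts the log2 change of CLN1 turns to -0.06. YDL218W had 144 ± 8.21 CPM with DMSO and 312 ± 15.9 with 1-NA-PP1 (n = 2), and ARO10 had 317 ± 12.1 and 191 ± 6.01. As groups, Hsf1 chaperone genes, ribosomal protein genes and Gcn4 targets were lower and G1/S genes higher, directions that turn with the deposited factor file for the first 3 (medians 1.62, 1.63 and 1.70) and with the factors behind the normalised counts for the last (median -0.36). These 4 lists did not pass with an estimated correlation (adjusted p = 0.185, 0.662, 0.472 and 0.28).

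YDL218W rose by a log2 change of 1.11 (SE 0.076, adjusted p = 0.00191). PDC6, a minor pyruvate decarboxylase gene, rose by 1.25 from 16.4 ± 1.98 to 39 ± 8.27 CPM, and HAP4 by 0.79 from 351 ± 42 to 606 ± 30.8 CPM. The polyamine exporter gene TPO2 rose by 0.68, the zinc finger gene STP4 by 0.66, the kinase gene RCK1 by 0.61, CLN1 by 0.56, NCA3 by 0.55, the cell wall gene PIR3 by 0.49 and the oligopeptide transporter gene OPT2 by 0.44, each with adjusted p = 0.0447, as for PDC6 and HAP4. With the factors behind the deposited normalised counts CLN1 had -0.06, NCA3 -0.06, PIR3 -0.13 and OPT2 -0.18. ARO9, on chromosome VIII at 375679 to 377364 with an antisense neighbour, had a log2 change of -0.92 (SE 0.082) and ARO10 of -0.73 (SE 0.068), both with adjusted p = 0.00684. At adjusted p = 0.0447, ARG4 had -0.76, CCP1 -0.62, LST8, a TOR complex subunit gene, -0.57, and SML1, an inhibitor of ribonucleotide reductase, -0.51. ARG4 and LST8 have antisense neighbours. For each of these 16 genes both 1-NA-PP1 libraries lay beyond both DMSO libraries. Their calls did not survive leaving out 1 library, apart from that of YDL218W, which was lost without DMSO replicate 1 (1.06) and 1-NA-PP1 replicate 2 (1.07) and held without the other 2. ARO10 then had -0.69 without DMSO replicate 1, -0.76 without DMSO replicate 2 or 1-NA-PP1 replicate 1 and -0.69 without 1-NA-PP1 replicate 2.

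**Figure D2:**
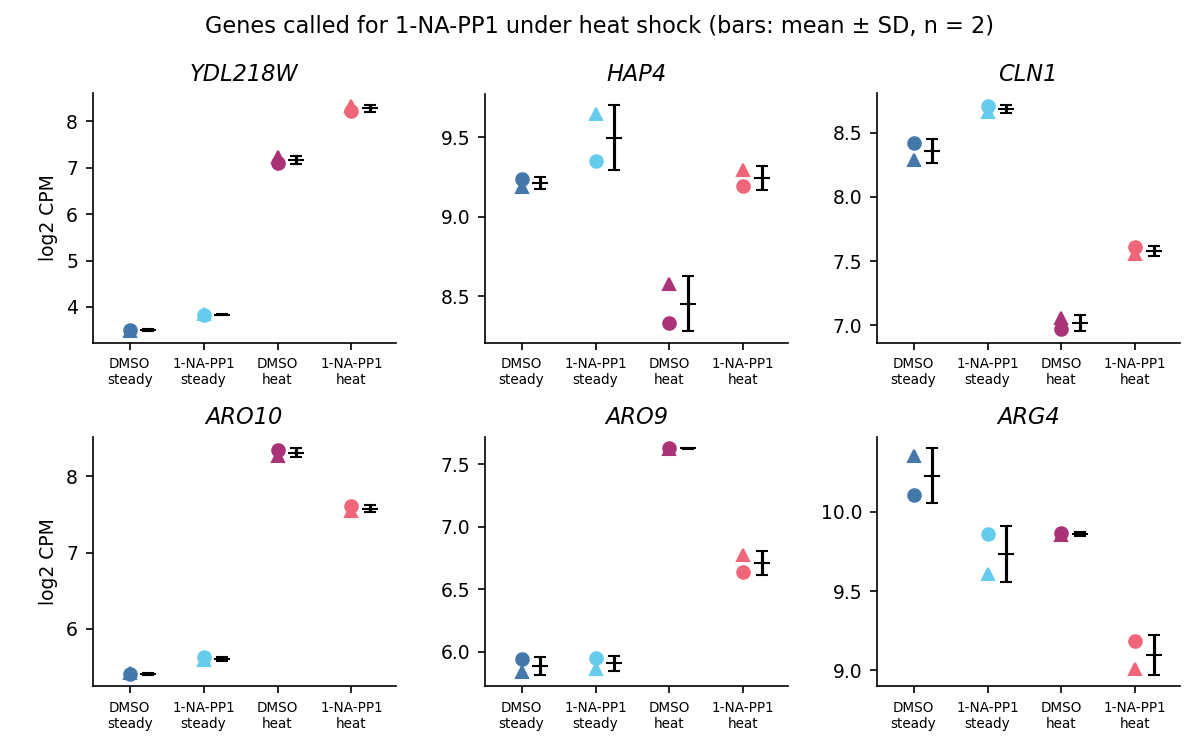
Log2 CPM of YDL218W, HAP4, CLN1, ARO10, ARO9 and ARG4 in each of the 8 libraries, with bars for the mean and SD of 2 libraries per group; vertical axes differ between genes and do not start at 0. Under heat shock YDL218W lies at 144 ± 8.21 CPM with DMSO and 312 ± 15.9 with 1-NA-PP1.

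Hsf1 core targets had a median log2 change of -0.37 with 1-NA-PP1 under heat shock, with 22 of 22 negative, 0 called over all genes and 20 lower adjusted over the list alone (adjusted p = 2.61e-26, and 0.185 with an estimated correlation). SSA4 had 2540 ± 465 CPM with DMSO and 1630 ± 157 with 1-NA-PP1 (log2 change -0.64, adjusted p = 0.0967), and HSP104 had 5660 ± 795 and 4080 ± 58.4 (-0.47, adjusted p = 0.105). The mitochondrial chaperone genes HSP78 and HSP60, the latter with an antisense neighbour, had -0.61 and -0.42, both with adjusted p = 0.0703, and BTN2 had -0.31 (adjusted p = 0.151). Among markers of general stress, HSP12 had -0.10, HSP26 0.36 and CTT1 0.64, with adjusted p of 0.886, 0.557 and 0.255. HSP12 turned to 0.17 without DMSO replicate 1, 0.13 without 1-NA-PP1 replicate 1 and 1.92 with the deposited factor file. The factors behind the normalised counts turned HSP26 to -0.29 and CTT1 to -0.001. The general stress list as a whole did not pass (adjusted p = 0.793; median -0.10, mean 0.02). Ribosomal protein genes had a median of -0.35, with 133 of 134 negative and 0 called by either count (adjusted p = 5.51e-22, and 0.662 with an estimated correlation). RPS25A, which has a near-identical paralog, had -0.68 (adjusted p = 0.0703). Gcn4 targets had a median of -0.28, with 33 of 37 negative, 1 lower over all genes, ARG4, and 11 lower adjusted over the list alone (adjusted p = 4.01e-14, and 0.472 with an estimated correlation). HIS1, of histidine synthesis, had -0.45 (adjusted p = 0.0703). Yap1 targets had a median of -0.21, with 18 of 19 negative, 1 lower over all genes, CCP1, and 8 adjusted over the list alone (adjusted p = 1.42e-08, and 0.185 with an estimated correlation). GRE2, a methylglyoxal reductase gene, had -0.38. RNA polymerase II subunits had a median of -0.21, with 10 of 11 negative and 3 lower adjusted over the list alone (adjusted p = 0.0028, and 0.326 with an estimated correlation), and RPB5 had -0.33. Without DMSO replicate 1 or 1-NA-PP1 replicate 1 the polymerase II median was -0.13. With the factors of the deposited factor file these 5 medians turned to 1.62, 1.63, 1.70, 1.77 and 1.79, in the order given here, as that file shifts the median of all genes to 1.98.

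G1/S genes, which prepare DNA replication, had a median of 0.28 with 1-NA-PP1 under heat shock, with 20 of 21 positive, 1 higher over all genes, CLN1, and 11 adjusted over the list alone (adjusted p = 4.16e-14, and 0.28 with an estimated correlation). RNR1, the ribonucleotide reductase gene, with an antisense neighbour, had 65.9 ± 0.425 CPM with DMSO and 102 ± 0.328 with 1-NA-PP1 (log2 change 0.62, adjusted p = 0.0612). G2/M genes, of mitosis, had a median of 0.15, with 10 of 12 positive and 6 higher adjusted over the list alone (adjusted p = 0.00203, and 0.326 with an estimated correlation). CDC5 and CDC20, a mitotic kinase gene and an activator of anaphase, had 0.25 and 0.20. Glucose-repressed genes had a median of 0.19, with 21 of 25 positive and 0 called by either count (adjusted p = 0.00398, and 0.662 with an estimated correlation), and PCK1, of glucose synthesis, had 0.50. Ste12 targets of mating and filamentous growth had a median of 0.15, with 11 of 13 positive, 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.00644, and 0.529 with an estimated correlation). TEC1 and AGA1 had 0.36 and 0.48. With the factors behind the deposited normalised counts, which shift the median of all genes to -0.62, these 4 medians turned to -0.36, -0.47, -0.44 and -0.45. The same factors turned CDC5, CDC20, PCK1, TEC1 and AGA1 to -0.37, -0.42, -0.11, -0.26 and -0.12. The Ste12 call was lost without DMSO replicate 1 (adjusted p = 0.0511) and without 1-NA-PP1 replicate 1 (median 0.09, adjusted p = 0.124), and its median was 0.23 without either replicate 2. The glucose-repressed call was lost without DMSO replicate 2 (adjusted p = 0.186), and its median was 0.37 without DMSO replicate 1 and 0.30 without 1-NA-PP1 replicate 1.

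SSN3 had a log2 change of 0.28 (adjusted p = 0.212), SSN8 of 0.21 (adjusted p = 0.321) and TRP1 of 0.24 (adjusted p = 0.469) under heat shock, which turned to -0.33, -0.40 and -0.38 with the factors behind the normalised counts. The authors' heat shock response genes, not independent evidence, had a median of -0.11, with 16 of 22 negative, 0 called over all genes and 4 lower adjusted over the list alone (adjusted p = 0.0149, and 0.652 with an estimated correlation), and 1.86 with the factor file. That median was -0.01 and -0.27 without DMSO replicates 1 and 2, and 0.03 and -0.22 without 1-NA-PP1 replicates 1 and 2. Their induced genes had a median of -0.12 and did not pass (adjusted p = 0.143).

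In edgeR 16 of 4901 genes were called for 1-NA-PP1 under heat shock, 10 higher and 6 lower, and 730 had an unadjusted p under 0.05. The count was 0 without DMSO replicate 1, 1 without DMSO replicate 2, 1 without 1-NA-PP1 replicate 1 and 0 without 1-NA-PP1 replicate 2. DESeq2 called 230, including all 16, edgeR on the 4 heat shock libraries alone 47, including the same 16, and voom with quality weights 65. Of 26 lists 9 passed camera and 0 with an estimated correlation. Leaving out a library added calls for ribosome biogenesis (lower, adjusted p = 0.000378 without DMSO replicate 1 and 0.00502 without 1-NA-PP1 replicate 1), polymerases I and III (lower, 0.0178 and 0.0472 without the same), respiration (higher, 0.006) and iron (higher, 8.77e-06) without DMSO replicate 1, trehalose and glycogen (lower, 0.00753 and 0.0278) without either replicate 2, proteasome (lower, 0.0135) without DMSO replicate 2, mating type a (higher, 0.0131) without 1-NA-PP1 replicate 1 and meiosis genes (higher, 0.0471) without 1-NA-PP1 replicate 2.

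Both inhibitor comparisons, which share no library, were set side by side to ask which genes respond to 1-NA-PP1 at both temperatures. In edgeR 0 genes were called in both, since 0 were called at steady state, while DESeq2 called 46 higher and 48 lower in both, where independent lists would share 11.2 and 11.5, and 5 in opposite directions. The edgeR fit with 1-NA-PP1 steady state replicate 2 alone had shared calls too. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.376 and Spearman rho = 0.365, and 62.8% of genes had the same sign. Pearson r was 0.158 without DMSO heat shock replicate 2 and 0.187 without 1-NA-PP1 heat shock replicate 2. Among the lists, Hsf1 targets, ribosomal proteins, Gcn4 targets, Yap1 targets and RNA polymerase II subunits were lower as groups in both, and G1/S and glucose-repressed genes were higher in both; under heat shock the deposited factor file turns the former and the factors behind the normalised counts the latter, and at steady state the deposited factors turn G1/S genes (-0.14). With an estimated correlation 0 lists passed in either comparison, the smallest adjusted p being 0.45 at steady state and 0.185 under heat shock.

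Heat shock with DMSO shows what 12 minutes at 37 °C does without the inhibitor. As groups, genes of the general stress response, proteasome, iron uptake and cell wall were higher, and genes of the cell cycle, histones and ribosomes were lower, though not every member was called. With an estimated correlation 0 of the 26 lists passed, the smallest adjusted p being 0.0639, for G2/M genes. HSP26, a small chaperone gene, rose from 31.6 ± 6.37 to 402 ± 1.44 CPM (n = 2), and PAI3, an inhibitor of the vacuolar protease Pep4, from 5.93 ± 0.312 to 154 ± 53.6 CPM. CLB6, a cyclin gene of DNA replication, fell from 43.7 ± 3.84 to 3.77 ± 1.51 CPM, and RNR1 from 404 ± 39 to 65.9 ± 0.425 CPM. Among chaperone genes of Hsf1, SSA4 rose, with 914 ± 47.7 and 2540 ± 465 CPM.

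PAI3 rose by a log2 change of 4.70 (SE 0.335, adjusted p = 1.77e-05), and HSP26 by 3.67 (SE 0.294, adjusted p = 3.19e-05). YDL218W rose by 3.68 (SE 0.085, adjusted p = 2.85e-07), PDC6 by 3.94, GRE1, a stress-induced hydrophilin gene, by 3.74, the peroxisomal catalase gene CTA1 by 3.42 and ARO10 by 2.90. CLB6 fell, with a log2 change of -3.56 (SE 0.21, adjusted p = 6.56e-06), as did the glycogen synthase gene GSY1 with -2.91 (SE 0.264, adjusted p = 6.15e-05) and RNR1, with an antisense neighbour, with -2.615 (SE 0.103, adjusted p = 1.55e-06). Falls of -2.83 for URA1, of pyrimidine synthesis, -2.81 for the zinc transporter gene ZRT1 and -2.70 for POL30, the replication clamp PCNA, were called too.

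General stress genes rose as a group (23 tested, 19 called higher over all genes and 20 adjusted over the list alone, 0 lower, median 1.46; adjusted p = 5.79e-10, and 0.543 with an estimated correlation). CTT1 rose by 2.06, HSP12 by 1.81, the aldehyde dehydrogenase gene ALD4 by 1.61 and the cell wall gene SPI1 by 1.59. Hsf1 core targets rose as a group (22 tested, 15 higher and 2 lower by either count, median 0.36; adjusted p = 0.00171, and 0.638 with an estimated correlation). SSA4 rose by 1.47, HSP78 by 1.25, HSP60 by 1.07, HSP104 by 0.64 and BTN2 by 0.37, while CUR1 fell by 0.49. The BTN2 call was lost without DMSO steady state replicate 2 (0.35) and DMSO heat shock replicate 1 (0.25). With the deposited factors in edgeR HSP104 (0.32) and BTN2 (0.06) lost their calls. Trehalose and glycogen genes rose as a group (8 higher and 2 lower over all genes, 8 and 3 adjusted over the list alone, median 0.66; adjusted p = 0.0333, and 0.734 with an estimated correlation). NTH2 and NTH1, which break down trehalose, rose by 1.39 and 1.08. Proteasome genes rose as a group (32 of 32 positive, 23 higher and 0 lower by either count, median 0.39; adjusted p = 0.000197, and 0.648 with an estimated correlation), with RPN2 up by 1.04. The trehalose and glycogen call was lost without DMSO steady state replicate 2 (adjusted p = 0.0626) and DMSO heat shock replicate 1 (adjusted p = 0.113).

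Iron regulon genes, which bring iron into the cell, rose as a group on heat shock with DMSO (23 tested, 18 higher and 1 lower over all genes, 19 and 1 adjusted over the list alone, median 0.94; adjusted p = 6.59e-07, and 0.543 with an estimated correlation). CCC2, a copper transporter needed for iron uptake, rose by 1.63 from 255 ± 9.22 to 787 ± 38.6 CPM and ARN1, a siderophore transporter, by 1.53, while ISU2, of iron-sulfur cluster assembly, fell by 0.44. Cell wall integrity genes rose as a group (18 tested, 14 higher and 3 lower by either count, median 0.55; adjusted p = 5.61e-05, and 0.481 with an estimated correlation). The wall protein genes PIR3 and PIR1 rose by 1.49 and 1.35, and CIS3 (-1.18) and GAS1 (-0.59) fell. Yap1 targets had a median of 0.06, with 9 higher and 3 lower by either count, and -0.14 with library totals and -0.24 with the deposited factors (adjusted p = 0.0462, and 0.633 with an estimated correlation). CCP1 rose by 1.32 and the thioredoxin gene TRX2, with an antisense neighbour, fell by 0.49. The Yap1 median was 0.16 without DMSO steady state replicate 2, and the call was lost without DMSO steady state replicate 1 (median 0.02, adjusted p = 0.107), DMSO heat shock replicate 1 (adjusted p = 0.0615) or replicate 2 (adjusted p = 0.0527).

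Histone genes fell as a group (10 of 10 lower by either count, median -1.65; adjusted p = 8.89e-11, and 0.151 with an estimated correlation), with HHF1 at -1.99 and HTB1 at -1.67, each of which has a near-identical paralog. G1/S genes fell (21 tested, 0 higher and 19 lower by either count, median -1.42; adjusted p = 2.08e-25, and 0.151 with an estimated correlation), as did G2/M genes (12 tested, 0 higher and 11 lower by either count, median -1.36; adjusted p = 1.51e-19, and 0.0639 with an estimated correlation). TOS4, a G1/S gene, had -2.38, and the mitotic genes KIN3 and CDC20 had -1.81 and -1.57; TOS4 and KIN3 have antisense neighbours. Ribosomal protein genes fell as a group (134 tested, 0 higher and 102 lower over all genes, 109 lower adjusted over the list alone, median -0.69; adjusted p = 2.13e-09, and 0.734 with an estimated correlation), with RPL30 at -1.40 and RPS22B, which has a near-identical paralog, at -1.04. Ribosome biogenesis factors fell as a group (48 tested, 0 higher and 20 lower over all genes, 19 lower adjusted over the list alone, median -0.44; adjusted p = 0.00667, and 0.795 with an estimated correlation), with NOP15 at -1.25 and NHP2 at -1.03. Polymerase I and III subunits fell as a group (18 tested, 10 lower over all genes, 12 adjusted over the list alone, median -0.53; adjusted p = 0.0247, and 0.734 with an estimated correlation), with RPA12 at -1.13 and RPC82, which has an antisense neighbour, at -1.09. Respiration genes fell as a group (37 tested, 2 higher and 16 lower by either count, median -0.22; adjusted p = 0.0462, and 0.734 with an estimated correlation), with ATP17 and CYC1, both with antisense neighbours, at -0.99 and -0.95. Without DMSO heat shock replicate 1 the calls of ribosome biogenesis (adjusted p = 0.101) and polymerases I and III (adjusted p = 0.0843) were lost, and that of respiration without DMSO steady state replicate 2 (adjusted p = 0.0888) or heat shock replicate 2 (adjusted p = 0.128), with a median of -0.36 without DMSO heat shock replicate 1.

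**Figure D3:**
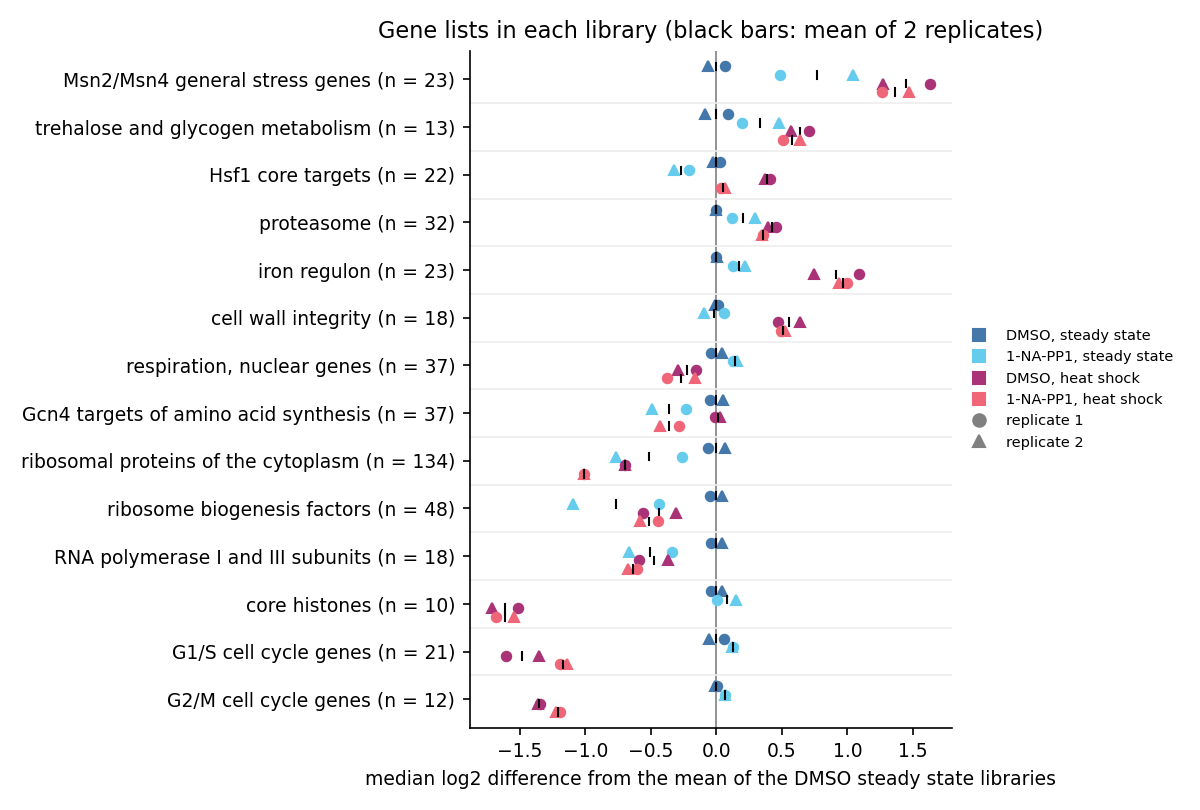
Median log2 difference of 14 gene lists in each library from the mean of the DMSO steady state libraries, one point per library and a black bar for the mean of 2 libraries. G1/S genes lie at -1.61 and -1.36 in the DMSO heat shock libraries and at 0.13 and 0.12 in the 1-NA-PP1 steady state libraries. With the deposited factors their median change with 1-NA-PP1 at steady state was -0.14, where that of all genes was -0.21.

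TRP1 rose by 0.69 on heat shock with DMSO (adjusted p = 0.00353), while SSN3 had -0.16 (adjusted p = 0.172) and SSN8 0.14 (adjusted p = 0.196; -0.06 with library totals and -0.17 with the deposited factors); with the deposited factors in edgeR TRP1 lost its call (0.36) and SSN3 gained one (-0.47). The authors' heat shock response genes, not independent evidence, had a median of 1.24, with 17 of 22 higher over all genes (adjusted p = 7.19e-07, and 0.222 with an estimated correlation). All 13 of their induced genes were higher, with a median of 1.59 (adjusted p = 5.99e-09, and 0.222 with an estimated correlation). In all, 2866 of 4901 genes were called, 1450 higher and 1416 lower, and 496 at 2-fold or more, 259 higher and 237 lower. The balance of directions follows the scaling: library totals alone gave 873 higher and 2215 lower with a median over all genes of -0.21, and the deposited factors 425 higher and 2051 lower with a median of -0.32. The authors' deposited table has 437 genes higher and 2059 lower at adjusted p under 0.05, with a median of -0.32, and its log2 changes correlated with those of edgeR at r = 0.9998 across genes, which are not independent replicates. Of 26 lists 14 passed camera and 0 with an estimated correlation, and other Mediator subunits passed without DMSO heat shock replicate 2 (lower, adjusted p = 0.0337 without it and 0.0869 with all).

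Heat shock with 1-NA-PP1 asks how cells with inhibited Srb10 respond to 37 °C. As groups, genes of general stress, iron uptake and the cell wall were higher, and cell cycle, histone, ribosomal protein and respiration genes were lower. Not every member was called. With the deposited factors the cell wall median was -0.06, where that of all genes was -0.66. Only the G2/M genes passed with an estimated correlation (adjusted p = 0.0457). YDL218W rose from 14.2 ± 0.0474 to 312 ± 15.9 CPM (n = 2) and HSP26 from 71.9 ± 29.1 to 518 ± 117. GSY1 fell from 140 ± 21.6 to 13.1 ± 1.5 CPM and MCD1, a cohesin subunit gene, from 390 ± 27 to 67 ± 1.57. SSA4 rose from 1020 ± 142 to 1630 ± 157 CPM.

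PDC6 rose by 4.51 (SE 0.203, adjusted p = 2.64e-06) and YDL218W by 4.45 (SE 0.087, adjusted p = 7.58e-08) on heat shock with 1-NA-PP1. GRE1 rose by 3.91, PAI3 by 3.20, CTA1 by 2.89, HSP26 by 2.85 and RCK1 by 2.61. Falls were -3.42 for GSY1 (SE 0.27, adjusted p = 3.42e-05), -2.99 for RSB1, -2.86 for CLB6 and -2.54 for MCD1. General stress genes rose as a group (15 higher and 1 lower by either count, median 0.72; adjusted p = 2.56e-05, and 0.586 with an estimated correlation), with CTT1 up by 1.57, SPI1 by 1.04 and HSP12 by 0.75. Without 1-NA-PP1 steady state replicate 1 the list's median was 0.45 and HSP12 lost its call (0.45), as it did without 1-NA-PP1 heat shock replicate 2 (0.49). Hsf1 core targets rose as a group (13 higher and 2 lower by either count, median 0.33, but -0.33 with the deposited factors; adjusted p = 0.0226, and 0.707 with an estimated correlation). That call was lost without 1-NA-PP1 steady state replicate 2 (adjusted p = 0.0829). HSP78 rose by 0.98, HSP60 by 0.93, SSA4 by 0.67 and HSP104 by 0.40, CUR1 fell by 0.57, and BTN2 had 0.20 (adjusted p = 0.0796; -0.43 with the deposited factors). HSP104 lost its call without 1-NA-PP1 heat shock replicate 1 (0.41) or 2 (0.38). With the deposited factors in edgeR the calls of HSP78 (0.32), HSP60 (0.27), SSA4 (0.05), CUR1 (-1.22), CTT1 (0.97), SPI1 (0.43) and HSP12 (0.15) were lost, and HSP104 turned to -0.25. In DESeq2 with these factors CUR1 and CTT1 kept theirs.

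Iron regulon genes rose as a group on heat shock with 1-NA-PP1 (18 higher and 1 lower over all genes, 18 and 2 adjusted over the list alone, median 0.90; adjusted p = 1.18e-07, and 0.458 with an estimated correlation), with ARN1 up by 1.82 and CCC2 by 1.29. Cell wall integrity genes rose as a group (13 higher and 2 lower over all genes, 14 and 2 adjusted over the list alone, median 0.58, but -0.06 with the deposited factors; adjusted p = 2.5e-05, and 0.454 with an estimated correlation), with PIR3 up by 1.73, PIR1 up by 1.15 and CIS3 at -1.22. Histone genes fell (10 of 10 lower by either count, median -1.69; adjusted p = 8.61e-14, and 0.122 with an estimated correlation), with HHF1 at -2.19 and HTB1 at -1.64. G1/S genes fell (20 of 21 lower by either count, median -1.27; adjusted p = 1.95e-22, and 0.122 with an estimated correlation), with TOS4 at -2.08. G2/M genes fell (11 of 12 lower by either count, median -1.29; adjusted p = 2.28e-19, and 0.0457 with an estimated correlation, the call that held), with SWI5 at -1.78 and KIN3 at -1.60, both with antisense neighbours. Ribosomal protein genes fell as a group (74 of 134 lower over all genes and 75 adjusted over the list alone, median -0.54; adjusted p = 1.43e-05, and 0.855 with an estimated correlation), with RPL30 at -1.5 and RPS22B at -1.14; without 1-NA-PP1 steady state replicate 1 the median was -0.24. Respiration genes fell as a group (1 higher and 24 lower by either count, median -0.43; adjusted p = 0.00155, and 0.598 with an estimated correlation), with CYC1 at -1.20 and QCR10 at -0.93. With the deposited factors in edgeR the calls of ARN1 (1.19), CCC2 (0.66), PIR3 (1.10), PIR1 (0.51) and QCR10 (-1.54) were lost, and in DESeq2 with these factors those of CCC2 and PIR1.

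Ribosome biogenesis factors did not pass on heat shock with 1-NA-PP1 (48 tested, 3 higher and 1 lower over all genes, 0 adjusted over the list alone, median 0.18; adjusted p = 0.362). Without 1-NA-PP1 steady state replicate 1 they were higher as a group (adjusted p = 1.22e-05), as were Gcn4 targets (0.025), Yap1 targets (0.0392) and ergosterol genes (0.0493), and multidrug resistance genes were lower (0.00211). Proteasome genes did not pass (10 higher over all genes, 8 adjusted over the list alone, median 0.15; adjusted p = 0.151), and did without 1-NA-PP1 steady state replicate 2 (0.0192), with RPN2 up by 0.66. SSN3 fell by 0.27 (adjusted p = 0.0364), a call lost without 1-NA-PP1 steady state replicate 2 (-0.16) and without 1-NA-PP1 heat shock replicate 1 (-0.26) or 2 (-0.30). SSN8 had 0.05 (adjusted p = 0.663), but -0.12 with library totals, -0.56 with the deposited factors and -0.05 and -0.01 without replicate 1 of 1-NA-PP1 at steady state and under heat shock. TRP1 rose by 0.65 (adjusted p = 0.0054). With the deposited factors the calls of RPN2 (0.04), SSN3 (-0.89) and TRP1 (0.03) were lost. The authors' heat shock response genes, not independent evidence, had a median of 0.50, with 11 higher and 1 lower of 22, and -0.11 with the deposited factors (adjusted p = 0.00575, and 0.466 with an estimated correlation); without 1-NA-PP1 steady state replicate 2 the median was 0.77. Their induced genes had a median of 0.77, with 10 of 13 higher over all genes and 11 adjusted over the list alone (adjusted p = 0.000134, and 0.466 with an estimated correlation).

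In edgeR 2617 of 4901 genes were called for heat shock with 1-NA-PP1, 1241 higher and 1376 lower, and 391 at 2-fold or more, 189 higher and 202 lower. Library totals alone gave 748 higher and 2034 lower with a median over all genes of -0.18, and the deposited factors 23 higher and 183 lower with a median of -0.66. The authors' deposited table has 56 genes higher and 886 lower with a median of -0.66, and correlated with edgeR at r = 0.999 across genes. Of 26 lists 10 passed camera and 1 with an estimated correlation.

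Both heat shock comparisons, which share no library, had 1045 genes called higher and 1088 called lower in both and 0 called in opposite directions, where independent lists would share 367.2 and 397.6. Without 1-NA-PP1 steady state replicate 1, 120 genes were called in opposite directions. Library totals alone gave 595 higher and 1752 lower in both and 3 in opposite directions, where independent lists would share 133.2 and 919.3. Log2 changes correlated with Pearson r = 0.892 and Spearman rho = 0.852 across genes, which are not independent replicates, with a slope of 0.821 of the change with 1-NA-PP1 on that with DMSO. PDC6, YDL218W, PAI3, HSP26 and GRE1 were among the genes that rose in both, and CLB6 and GSY1 among those that fell in both.

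**Figure D4:**
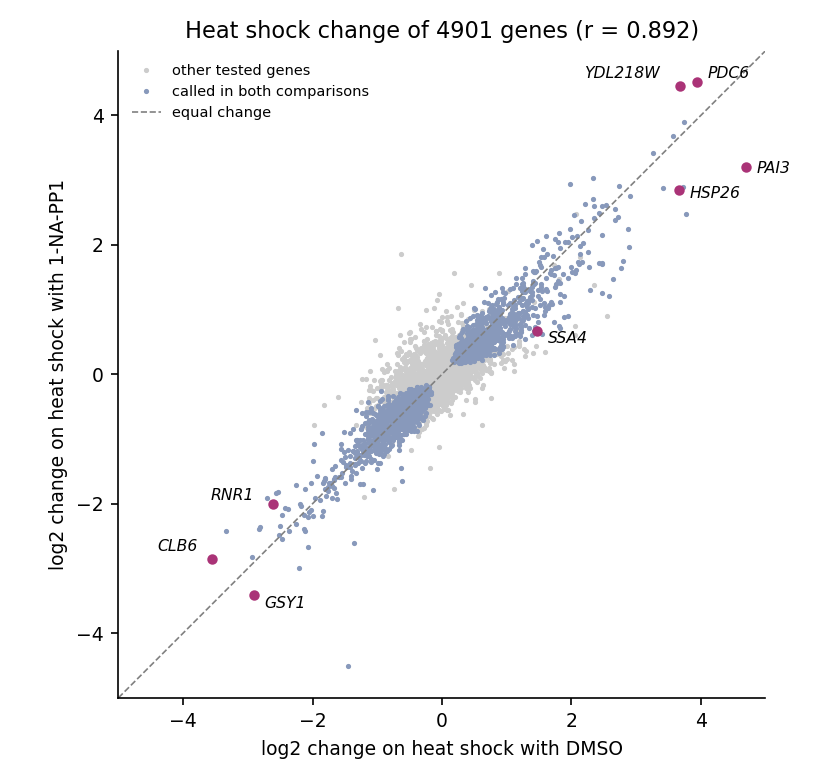
Log2 change on heat shock with DMSO (horizontal) and with 1-NA-PP1 (vertical) for 4901 genes, one point per gene, coloured where called in both comparisons; the dashed line marks equal changes. Pearson r is 0.892, and PAI3 lies at 4.70 and 3.20, CLB6 at -3.56 and -2.86.

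The last comparison asked which heat shock changes differ between 1-NA-PP1 and DMSO. ARO10, the decarboxylase gene of aromatic amino acid breakdown, rose by less with 1-NA-PP1: it went from 42.6 ± 0.422 to 317 ± 12.1 CPM with DMSO and from 48.8 ± 0.801 to 191 ± 6.01 CPM with 1-NA-PP1 (n = 2). General stress, trehalose and glycogen, proteasome and multidrug resistance genes had lower changes as groups with 1-NA-PP1, each with adjusted p = 0.668 with an estimated correlation. Ribosome biogenesis and polymerase I and III genes had higher changes as groups, with adjusted p = 0.668 as well, as did ribosomal protein genes (adjusted p = 0.821), whose median turned to -0.07 without 1-NA-PP1 steady state replicate 2. For each gene, though not for the medians, the difference equals its change with 1-NA-PP1 under heat shock minus that at steady state; general stress genes had medians of -0.10, which did not pass, and 0.79 in these comparisons.

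ARO10 had a difference of log2 changes of -0.93 (SE 0.096, adjusted p = 0.0474), and every replicate difference with 1-NA-PP1 lay below every one with DMSO. The call held without either 1-NA-PP1 steady state library and was lost without any of the other 6, where the value was -0.92, -0.94, -0.84, -0.90, -0.90 and -0.84 without DMSO steady state, DMSO heat shock and 1-NA-PP1 heat shock replicates 1 and 2. General stress genes had a median difference of -0.55 (23 tested, 21 negative, 9 lower adjusted over the list alone; adjusted p = 3.44e-09, and 0.668 with an estimated correlation). PAI3 had -1.498, HSP12 -1.06, HSP26 -0.82, SPI1 -0.55 and CTT1 -0.49, with adjusted p from 0.357 to 0.49. Trehalose and glycogen genes had -0.51 (13 of 13 negative; adjusted p = 1.08e-05, and 0.668 with an estimated correlation), with UGP1, which has an antisense neighbour, at -0.63 and TPS1 at -0.54. Proteasome genes had -0.29 (32 of 32 negative, 1 lower adjusted over the list alone; adjusted p = 5.81e-09, and 0.668 with an estimated correlation), with RPN9, which has an antisense neighbour, at -0.44. Multidrug resistance genes had -0.36 (9 of 9 negative; adjusted p = 0.00152, and 0.668 with an estimated correlation), with TPO1 at -0.36. Hsf1 core targets had -0.12 (17 of 22 negative; adjusted p = 0.0349, and 0.816 with an estimated correlation), with SSA4 at -0.80, HSP104 at -0.24 and BTN2 at -0.17. Respiration genes had -0.16 (27 of 37 negative; adjusted p = 0.0275, and 0.816 with an estimated correlation). Without 1-NA-PP1 steady state replicate 2 the medians were -0.35 for general stress, -0.33 for trehalose and glycogen, -0.19 for proteasome and -0.23 for multidrug resistance genes. Without DMSO heat shock replicate 1 they were -0.23 for trehalose and glycogen, -0.19 for proteasome, -0.03 for Hsf1 and -0.002 for respiration genes, and without 1-NA-PP1 heat shock replicate 1 they were -0.33 for trehalose and glycogen, -0.06 for Hsf1 and -0.04 for respiration genes.

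Ribosome biogenesis factors had a median difference of 0.65 (48 of 48 positive; adjusted p = 1.37e-24, and 0.668 with an estimated correlation), with KRR1 at 0.99 and EBP2 at 0.61. Polymerase I and III subunits had 0.48 (17 of 18 positive; adjusted p = 1.51e-07, and 0.668 with an estimated correlation), with RPC53 at 0.48. Ribosomal proteins had 0.16 (110 of 134 positive; adjusted p = 1.65e-05, and 0.821 with an estimated correlation), and without 1-NA-PP1 steady state replicate 2 the group's median turned to -0.07 and its call was lost (adjusted p = 0.14). Without that library ribosome biogenesis had 0.38 and polymerases I and III 0.24, and without 1-NA-PP1 steady state replicate 1 ribosome biogenesis had 1.03 and ribosomal proteins 0.44. G1/S genes had 0.15 (15 of 21 positive, 1 higher adjusted over the list alone; adjusted p = 0.000217, and 0.668 with an estimated correlation), with POL30 at 0.79 and RNR1 at 0.61, and a median of 0.31 without DMSO heat shock replicate 2 and 0.24 without 1-NA-PP1 heat shock replicate 1. Ste12 targets had 0.14 (11 of 13 positive; adjusted p = 0.0217, and 0.668 with an estimated correlation), and 0.27 and 0.25 without replicate 2 of DMSO and 1-NA-PP1 under heat shock. SSN3 had -0.11, SSN8 -0.09 and TRP1 -0.04. Their signs turned without 1 library: SSN3 and TRP1 without DMSO heat shock replicate 1 (0.01 and 0.18), SSN8 and TRP1 without 1-NA-PP1 steady state replicate 2 (0.01 and 0.12), and TRP1 and SSN8 without 1-NA-PP1 heat shock replicates 1 and 2 (0.13 and 0.02). The authors' heat shock response genes, not independent evidence, had -0.52 (21 of 22 negative; adjusted p = 2.52e-10, and 0.134 with an estimated correlation), and their induced genes -0.78 (13 of 13 negative, 8 lower adjusted over the list alone; adjusted p = 1.04e-09, and 0.134 with an estimated correlation). Without 1-NA-PP1 steady state replicate 2 the induced genes had -0.42, and without DMSO heat shock replicate 1 these lists had -0.31 and -0.49. Over all genes 0 members of these lists were called.

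In edgeR 1 of 4901 genes, ARO10, was called for a difference in its heat shock change, and 661 had an unadjusted p under 0.05, 278 higher and 383 lower. The count was 848 (440 higher, 408 lower) without 1-NA-PP1 steady state replicate 1, 2 without replicate 2 of that group and 0 without any other library, and DESeq2 called 24 (10 higher, 14 lower). Of 26 lists 11 passed camera and 0 with an estimated correlation. The Hsf1 call was lost without DMSO steady state replicate 2 (adjusted p = 0.0824), 1-NA-PP1 steady state replicate 1 (median -0.04, adjusted p = 0.519), DMSO heat shock replicate 1 (0.673), and 1-NA-PP1 heat shock replicate 1 (median -0.06, adjusted p = 0.0915) or 2 (median -0.07, adjusted p = 0.0674). The respiration call was lost without either replicate 1 of the steady state groups (adjusted p = 0.183 with DMSO and 0.0815 with 1-NA-PP1) and without either replicate 1 of the heat shock groups (0.709, and 0.138 with a median of -0.04), and the Ste12 call without replicate 1 of 1-NA-PP1 at steady state (0.214) or under heat shock (0.106). Lists that passed only without 1 library were Gcn4 targets (higher, 0.0103 without DMSO steady state replicate 1, 0.00215 without 1-NA-PP1 steady state replicate 1 and 0.0083 without 1-NA-PP1 heat shock replicate 2), glycolysis (lower, 0.0228 without 1-NA-PP1 steady state replicate 2 and 0.0172 without DMSO heat shock replicate 2), G2/M genes (higher, 0.0372 without 1-NA-PP1 steady state replicate 2) and the iron regulon (higher, 0.0241 without DMSO heat shock replicate 1).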

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

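Chosen only after the pattern was seen were thinning and tests of gene length, GC content, RNA from heat-shocked cells and the deposited factor file. Leaving out 1 library was fixed first. The results that stood out are tested differences in the heat shock change between 1-NA-PP1 and DMSO, and they are weighed with a pattern at steady state and with the deposited factor file. Each value is named as a log2 change at steady state or as a difference of heat shock changes (1-NA-PP1 minus DMSO), as a median for lists.

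At steady state, 1-NA-PP1 went with higher general stress genes (median log2 change 0.79) and lower ribosome biogenesis factors (median log2 change -0.72), more so in replicate 2. Without replicate 2 the medians were 0.49 and -0.44, which argues against that library as the whole source. Replicate 1 is then alone, so the spread is not measured. With all libraries the lists had adjusted p = 0.471 and 0.45 with an estimated correlation. Carried-over RNA of heat-shocked cells would lower the G1/S genes against others. Their median was 0.12 in replicate 2 and 0.13 in replicate 1, where the median change of all genes was 0.05. With the deposited factors it was -0.14 over both, and that of all genes was -0.21. G1/S genes thus lay above the median gene under both scalings, which argues against carried-over RNA as the source. Taking out a trend on gene length and GC content left medians of 0.69 and -0.78, though this trend held 0.2% of the variance over genes and moved a gene by a median of 0.046, so the test says little. An effect of Srb10 inhibition, an effect of 1-NA-PP1 on other kinases and a difference between the cultures stay open, since no strain without the sensitive form was measured.

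On heat shock, general stress genes had a median difference of -0.55 between the changes with 1-NA-PP1 and DMSO, with adjusted p = 0.668 with an estimated correlation. Thinning keeps expected ratios, so it cannot test depth, and left the list at -0.53 (adjusted p = 7.76e-10 at the preset correlation). Without 1-NA-PP1 steady state replicate 2 it had -0.35, which argues against that library as the whole source, though replicate 1 is then alone. For each gene, though not for the medians, the difference equals its change under heat shock minus that at steady state (list medians -0.10, which did not pass, and 0.79), so it does not tell a smaller response from a higher start. Whether Srb10 acts on the heat response itself stays open.

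ARO10 had a difference of -0.93. Its call held in DESeq2 (-0.91) and in voom with quality weights (-0.93). It was lost in edgeR with a replicate block (-0.93), DESeq2 factors (-0.91), library totals (-0.89), no filter (-0.87), a 2-fold minimum (-0.93) and thinned counts (-1.03). Without 1 library it was lost in 6 of 8 fits: -0.92 and -0.94 without DMSO steady state replicates 1 and 2, -0.84 and -0.90 without DMSO heat shock replicates 1 and 2, and -0.90 and -0.84 without 1-NA-PP1 heat shock replicates 1 and 2.

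With the factors of the deposited file for 1-NA-PP1 against DMSO under heat shock, 4855 genes were called, all higher. All 4 factors in that file equal those of the DMSO steady state and heat shock comparison. Only 1 of 4 equals the factor behind the deposited normalised counts, that of the first library, which is 1 in both. The factors behind those normalised counts put the median log2 change of all genes at -0.62, against 1.98 with the file, which argues against a general rise. A file saved under the wrong comparison is a candidate explanation.

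The other lists with a tested difference were trehalose and glycogen genes at -0.51, proteasome genes at -0.29, multidrug resistance genes at -0.36, Hsf1 targets at -0.12 and respiration genes at -0.16. Ribosome biogenesis factors had 0.65, polymerase I and III subunits 0.48, ribosomal proteins 0.16, G1/S genes 0.15 and Ste12 targets 0.14. With an estimated correlation 0 of the 11 lists called passed (adjusted p = 0.668 to 0.821). Ribosomal proteins turned to -0.07 without 1-NA-PP1 steady state replicate 2, and Hsf1 targets and respiration genes went to -0.03 and -0.002 without DMSO heat shock replicate 1. The authors' heat shock response genes had -0.52 and their induced genes -0.78 (adjusted p = 0.134 each with an estimated correlation), and neither list is independent of these samples.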

How the results depend on the processing

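Chosen after seeing the data were voom with quality weights, thinning, the factors behind the normalised counts, DESeq2 with deposited factors and crossed pairing; the cause was not tested unless the setting's construction shows it. The 0 calls at steady state became 986 with DESeq2, 749 with voom and 0 to 1712 when leaving out 1 library. The 16 calls under heat shock became 230 with DESeq2, 47 with only the libraries compared, 65 with voom, 4 with a replicate block, 2 at a 2-fold minimum, 4855 with the deposited factor file, 0 with the factors behind the normalised counts and 0 to 1 when leaving out 1 library. Heat shock calls with DMSO became 496 at a 2-fold minimum, and those with 1-NA-PP1 became 391 at that minimum, 206 with the deposited factors and 942 with DESeq2 and these factors. The 1 gene with a different heat shock change became 0 with DESeq2 factors, library totals, no filter, a replicate block, a 2-fold minimum or thinned counts, 24 with DESeq2 and 0 to 848 when leaving out 1 library. With an estimated correlation the called lists numbered 0, 0, 0, 1 and 0, where the preset one gave 14, 9, 14, 10 and 11. Genes called for 1-NA-PP1 at both temperatures were 94 with DESeq2 and 0 to 152 when leaving out 1 library, and those called for heat shock with both treatments 318 at a 2-fold minimum. With the deposited factor file under heat shock, the log2 change with 1-NA-PP1 turned to 1.08 for ARO9, 1.20 for ARG4, 1.24 for ARO10, 1.36 for CCP1, 1.40 for LST8, 1.47 for SML1, 1.57 for HSP60, 1.37 for HSP78, 1.31 for RPS25A, 1.51 for HIS1, 1.59 for GRE2, 1.65 for RPB5, 1.51 for HSP104, 1.35 for SSA4, 1.92 for HSP12 and 1.67 for BTN2. With the factors behind the normalised counts it turned to -0.056 for CLN1, -0.062 for NCA3, -0.13 for PIR3 and -0.18 for OPT2. Heat shock with 1-NA-PP1 turned to -0.25 for HSP104 with the deposited factors in both tools. These reversals follow from scaling, as each setting shifts all genes by 1 amount. Of the values, under alternatives, of the genes named in the text of each comparison, 2720 kept direction and side of the threshold, 199 lost a call, 153 gained one and 54 changed sign, 22 of them called in either fit and 32 in neither. Over the wider set of genes that the naming rule picks, 297 of 8660 values changed sign, called or not: 59 for 1-NA-PP1 under heat shock with the deposited factor file and 50 with the factors behind the normalised counts, and with the deposited factors 20 for 1-NA-PP1 at steady state, 21 for heat shock with 1-NA-PP1 and 11 with DMSO. Deviations of replicates with the same number correlated between groups at -0.31 to 0.264, so the numbers give no pairing, and a crossed pairing at steady state called 0 genes. Simulated recovery at 1.5-fold was 86.6% for 1-NA-PP1 at steady state, 79.1% under heat shock and 85.1% for heat shock with DMSO. For 1-NA-PP1 this does not hold in real data. Depth was not tested, and thinned counts gave 19 calls for 1-NA-PP1 under heat shock instead of 16.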

Other observations

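The test of Gcn4 targets in this part was chosen after the result was seen; the lists were fixed first. Genes that mark the mating type changed on heat shock. MF(ALPHA)1, which encodes the pheromone of this cell type and has an antisense neighbour, fell by 2.504 with DMSO, from 2880 ± 283 to 508 ± 40.4 CPM (n = 2, adjusted p = 2.64e-06), with a log2 change of -2.34 with 1-NA-PP1. STE3, the receptor gene of this cell type, fell too, with -1.33 and -1.01. All 3 alpha genes tested fell with DMSO (median -1.33) and with 1-NA-PP1 (median -1.01), too few for camera. Of 6 genes of the other mating type, 4 were called higher in each, with medians of 1.22 (adjusted p = 0.116) and 1.49 (adjusted p = 0.0305, and adjusted p = 0.566 with an estimated correlation). Their call with 1-NA-PP1 was lost without 1-NA-PP1 steady state replicate 1 (adjusted p = 0.0677) and without 1-NA-PP1 heat shock replicate 2 (adjusted p = 0.0855). They started low: STE2, the receptor gene of that type, with an antisense neighbour, rose from 10.4 ± 0.79 to 24.5 ± 2.79 CPM with DMSO, and BAR1 from 4.61 ± 0.128 to 8.34 ± 0.142. Of 5 genes of meiosis, 3 rose and 1 fell in each heat shock comparison (adjusted p = 0.613 and 0.432), among them IME1, the inducer of meiosis, which rose by 0.97 with 1-NA-PP1, a call lost with the deposited factors (0.37).

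Several groups went both ways on heat shock with DMSO and did not pass as lists. In glycolysis 12 genes rose and 2 fell (adjusted p = 0.197): the dehydrogenase gene TDH1 rose by 1.52 and the glucose transporter gene HXT3 fell from 672 ± 15.5 to 176 ± 2.22 CPM. Among glucose-repressed genes 10 rose and 7 fell (adjusted p = 0.923), with the acetyl-CoA synthetase gene ACS1, which has an antisense neighbour, up by 1.77, the peroxisomal oxidase gene POX1 up by 2.07 and MTH1, a regulator of glucose sensing, at -2.48. Gcn4 targets had 7 higher and 6 lower (adjusted p = 0.729), with SNZ1, of vitamin B6 synthesis and with an antisense neighbour, up by 1.95 and BAT1, a branched-chain aminotransferase, at -1.31. Ste12 targets had 3 higher and 6 lower (adjusted p = 0.613; median -0.16, mean 0.03), with AGA1 up by 0.92. Ergosterol genes had 14 higher and 2 lower (adjusted p = 0.248), with ERG25 up by 0.89 and ERG5 at -0.46. Phosphate genes had 5 higher and 1 lower (adjusted p = 0.333), with PHM8 up by 1.14, which has an antisense neighbour, and PHO8 up by 0.87. Genes of the unfolded protein response had 6 higher and 5 lower (adjusted p = 0.989; median 0.01, mean -0.05), and multidrug resistance genes 4 and 2 (adjusted p = 0.968; median 0.06, mean -0.05). Other Mediator subunits had 2 higher and 10 lower (adjusted p = 0.0869), with SOH1 at -0.65, and RNA polymerase II subunits 1 and 7 (adjusted p = 0.15), with RPB10, which has an antisense neighbour, at -0.64.

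Gcn4, the activator of amino acid synthesis genes, is a known target of Srb10, which marks it for breakdown, so a hypothesis was that inhibition may raise its targets. No rise was seen: the targets had medians of -0.37 at steady state and -0.28 under heat shock (adjusted p = 0.45 and 0.472 with an estimated correlation). With the deposited factor file the median under heat shock was 1.70, where that of all genes was 1.98. Over the fits without 1 of the libraries compared the median ran from -0.49 to -0.23, and as these fits share libraries and the test was set after the medians were seen, they are no independent test. How much Gcn4 protein the cells held was not measured.

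Some lists that did not pass had medians and means of opposite sign. At steady state these were cell wall integrity genes (-0.01 and 0.02), phosphate genes (0.04 and -0.03), ergosterol genes (0.03 and -0.003) and other Mediator subunits (0.01 and -0.002), and Ste12 targets had a median of 0.025 where camera's direction was down. Under heat shock, 1-NA-PP1 gave cell wall integrity genes -0.02 and 0.003 and other Mediator subunits 0.04 and -0.01. Heat shock with 1-NA-PP1 gave trehalose and glycogen genes 0.09 and -0.07 and Ste12 targets -0.14 and 0.14. In the difference of heat shock changes meiosis genes had 0.19 and -0.025, and other Mediator subunits had a median of -0.01 where camera's direction was up.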
